A study of Sus scrofa with 11 samples.

How the data were processed

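Samples of longissimus lumborum taken after slaughter were kept in RNAlater, and TruSeq libraries were made from 300 ng of total RNA per pig, per the labels' protocols. The series' design text names a HiScan SQ, 50 single-end cycles and 5 technical repetitions, and the deposited tables hold 1 column per pig. Replicate numbers were taken from the sample titles, and columns were joined to pigs by that number. The labels give each pig its own sample, so the replicates are animals. No number occurs in both groups, so nothing pairs the pigs.

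The deposited values are expected counts (estimated read counts per gene or isoform that are not normalized), deposited without decimals. CASAVA 1.8.2, FastQC, STAR, RSEM, edgeR and DESeq2 and the build Sscrofa10.2 are named in the submitters' processing notes, which give no roles or order. Genes numbered 25322, of which 6508 were at 0 in every pig, and isoforms 30585, of which 8918 were. There were 0 columns of other samples. Expected counts are rounded before such tests, which changed nothing here. Symbols came from a table of gene IDs, which named 11804 rows, and rows without a symbol held 20.68% of the counts. A RefSeq gene table of Sscrofa11.1, another build, was used for names and synonyms only. It names MYH1, MYH2, MYH4 and MYH7 but 0 genes as MYH6 or MYH8, while the gene table lists MYH6 and MYH8 but 0 IDs as MYH7, MYH2, MYH1, MYH4, MYL2 or ATP2A2. Counts on those myosin IDs are therefore uncertain, and 40 well-counted IDs had counts identical to those of another ID.

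Isoforms carry no gene name in the table. They were joined to genes through the order of rows and the counts: the isoforms of a gene were a run of rows whose counts summed to those of the gene, or fell short by at most 1 count per isoform, in each of the 11 pigs. The largest shortfall was 7 counts. Only isoforms with 1 possible gene were kept (28084), and 69 isoforms with counts had no such gene. The join is inferred from the values.

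Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr on the group, and the quasi-likelihood F test with a group term and no covariate, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are log2, fibre1 minus fibre2B. Standard errors are the size of the log2 fold change divided by the square root of F. CPM values are TMM-normalised. TMM factors ran from 0.718 in fibre1 pig 5 to 1.19. Isoforms were tested in the same way with their own factors, and isoform usage with diffSpliceDGE in genes with at least 2 tested isoforms. Lists were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, over lists with at least 5 tested genes. Camera with an estimated correlation and fry were also run. Single values were tested with a two-sided exact permutation test over all 330 splits of the pigs. The biological coefficient of variation was 29.8%.

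The 21 lists were fixed before the data were examined: slow-fibre and fast-fibre contractile and calcium genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, citrate cycle and pyruvate dehydrogenase, fatty acid uptake and oxidation, glycolysis and glycogen metabolism, fibre-type and mitochondrial regulators, muscle growth and proteolysis, immediate early, heat shock, interferon-stimulated and cytosolic ribosomal protein genes, and markers of adipocytes, fibroblasts, endothelium, smooth muscle and pericytes, immune cells, blood, satellite cells and nerve. Named genes were set by a rule fixed at the same time. It took the 8 largest folds in each direction among called genes with a symbol and at least 5 CPM in the higher group. MYH7, MYH2, MYH1, MYH4, TNNI1, TNNT1, MYL2, ATP2A2, PPARGC1A and PVALB were always to be named. Up to 3 members of each list with the smallest p were taken. So were the 5 isoforms with the smallest p in each direction whose gene has a symbol. For usage it took the 5 genes with a symbol and the smallest p. MYH8, MYL11 and VGLL2 were added after their values were seen. Some genes that this rule names are not reported here.

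Alternatives were other scaling factors, other filters (none, or at least 1 CPM in at least 4 pigs), DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersion, 1 surrogate variable from sva 3.50.0, leaving out mitochondrial and the 10 most abundant genes, and leaving out each pig. The pipeline was tested on simulated data with 200 changed genes. Of those changed 2-fold 29% were recovered and of those changed 4-fold 88%, over 11148 genes with 4.88% false calls. For isoforms it was 32% and 71% with 6.36% false calls, and for usage 51% at 4-fold with 5.56% false calls. The list test recovered the 1 list that was raised 1.5-fold. With no change 0 genes and 0 isoforms were called. At totals of 14832736 to 36374829 counts a 2-fold change was therefore often missed in the simulation of 7 against 4 pigs. Its dispersions were fitted without the group, which can lower the recovery. Genes were drawn independently of each other, while the estimated correlation in the 4 lists called in the real data was 0.51 to 0.73. The simulation therefore does not test false calls of lists with correlated genes. Read sequence, GC content and transcript length were not analysed here. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.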

Results

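RNA from the longissimus lumborum, a muscle of the back, was sequenced in 11 female pigs aged 23 weeks that had been grouped by the histology of the same muscle. In 7 pigs, called fibre1 here, type I fibres (slow and oxidative) made up more than 17% and type IIB fibres (fast and glycolytic) less than 70% of the fibres. In the other 4 pigs, called fibre2B, type I fibres made up less than 8% and type IIB fibres more than 70%. Each pig had 1 column of estimated counts per gene and per isoform. Total gene counts ran from 14832736 in fibre2B pig 14 to 36374829 in fibre1 pig 12, and the lowest chi-square per degree of freedom between any 2 pigs was 27.8, so no pair agreed within sampling noise. Pairwise Spearman correlations of log2 CPM over genes were 0.914 to 0.979. The first principal component held 30.3% of the variance and the second 17.3%. The 10 most abundant nuclear genes took 45.2% of the counts in fibre1 pig 5 and 44.1% in fibre1 pig 6, against 29.5% to 36.8% in the other 9 pigs.

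The first comparison asked which genes differ in expression between muscles with many and with few type I fibres. The largest fold among the named genes higher in fibre1 was that of the ID listed as MYH6 (ENSSSCG00000002029), a cardiac myosin heavy chain gene closely related to the slow-fibre gene MYH7. It had 5563 ± 4949 CPM in fibre1 (SD, n = 7) and 1134 ± 591 CPM in fibre2B (n = 4), a log2 fold change of 2.29 ± 0.59 (SE; edgeR adjusted p = 0.034). That call was lost without fibre1 pig 2 (adjusted p = 0.051), pig 5 (0.054) or pig 6 (0.056), and without fibre2B pig 10 (0.063), pig 11 (0.066), pig 14 (0.100) or pig 16 (0.063). EHBP1L1 had 170 ± 46.4 against 55.1 ± 7.81 CPM, a log2 fold change of 1.62 ± 0.22 (adjusted p = 0.012), and lost its call only without fibre2B pig 14 (adjusted p = 0.057). On the other side, MSTN, which encodes myostatin, an inhibitor of muscle growth, had 1.93 ± 1.28 CPM in fibre1 and 5.48 ± 2.49 CPM in fibre2B, a log2 fold change of -1.49 ± 0.41 (adjusted p = 0.040). HBB, a beta globin gene of red blood cells, had 269 ± 138 against 647 ± 229 CPM, a log2 fold change of -1.27 ± 0.35 (adjusted p = 0.041). The MSTN call was lost without fibre1 pig 1, 2, 5, 6 or 17 and without fibre2B pig 10, 14 or 16 (adjusted p from 0.054 to 0.116). The HBB call was lost without fibre1 pig 1, 2 or 17 and without any fibre2B pig (adjusted p from 0.052 to 0.153).

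By edgeR's quasi-likelihood test, 1021 of 11329 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 496 were higher in fibre1 and 525 higher in fibre2B. A change of at least 2-fold was seen in 145 and 154 of them, and the median size of the log2 change over the called genes was 0.82. The groups did not overlap in 855 genes, 7.55% of those tested, where chance gives 0.606% on average over all splits of the pigs. Genes vary together, so a single split can lie far from that average, and the share was not computed for other splits. Of the called genes 774 had a symbol. The other large folds higher in fibre1 were FAM53B (log2 fold change 2.18 ± 0.33), PROB1 (2.04 ± 0.37), HSPA1L of the heat shock protein 70 family (1.83 ± 0.52), NES, which encodes the intermediate filament protein nestin (1.65 ± 0.41), the kinesin gene KIF1C (1.58 ± 0.26) and RAPGEF1, an exchange factor for Rap1 (1.54 ± 0.23). Those higher in fibre2B were SAMD9 (-1.63 ± 0.45), BTNL9 of the butyrophilin-like family (-1.56 ± 0.33), the thiamine transporter gene SLC19A2 (-1.54 ± 0.28), the interferon-induced gene IFIT2 (-1.50 ± 0.39), BTAF1, which acts with the TATA-binding protein (-1.47 ± 0.36), and TMEM100 (-1.45 ± 0.21). Without fibre2B pig 14 SAMD9 had -0.94 (adjusted p = 0.203) and IFIT2 -0.79 (adjusted p = 0.164). SAMD9 also lost its call without fibre1 pig 1, 2, 5, 6 or 17 or fibre2B pig 10 or 16 (adjusted p from 0.052 to 0.072), and IFIT2 without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 10 (0.059 to 0.064). HSPA1L lost its call without fibre1 pig 2, 5, 6 or 7 or any fibre2B pig (0.056 to 0.112). NES lost it without fibre1 pig 2 or 6 or any fibre2B pig (0.054 to 0.079), and BTAF1 without fibre1 pig 2 or fibre2B pig 10, 14 or 16 (0.054 to 0.089). With all 11 pigs limma-voom did not call HSPA1L (adjusted p = 0.065), SAMD9 (0.061) or IFIT2 (0.064), and the robust quasi-likelihood test did not call HSPA1L (0.058). The other 7 genes named here lost theirs only without fibre2B pig 14, among leave-outs of a single pig (0.057 to 0.084). MYH6, MYH8 and HSPA1L belong to families of near-identical genes, and so does HBB, so their counts are uncertain.

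**Figure D1:**
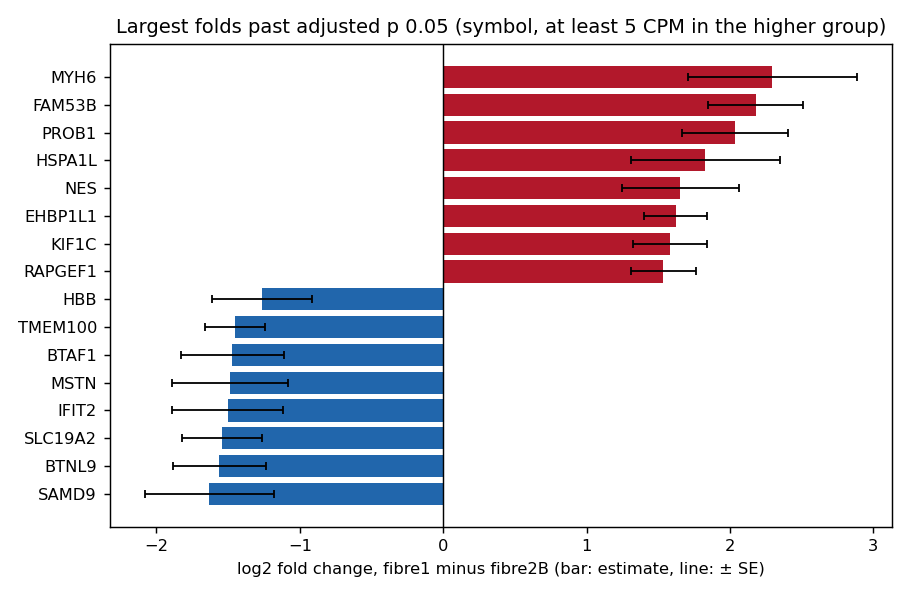
Log2 fold change, fibre1 minus fibre2B, of the genes with a symbol and at least 5 CPM in the higher group that had the largest folds in each direction past an adjusted p of 0.05. Bars start at 0, black lines give ± 1 SE, and red bars are higher in fibre1 (n = 7) and blue bars in fibre2B (n = 4), from MYH6 at 2.29 to SAMD9 at -1.63.

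The number of genes called rested on single pigs. With fibre2B pig 14 left out edgeR called 0 genes (2436 at an unadjusted p under 0.05). There DESeq2 called 784, limma-voom with quality weights 1095 and edgeR with 1 surrogate variable 129, and all 1021 genes kept their direction. Running these other settings without pig 14 was chosen after seeing the data. With all pigs they had called the most genes (1759, 1748 and 1628). Plain limma-voom and the other alternatives were not run without pig 14. The other splits of the pigs were not run with these settings, so their calls without pig 14 have no such comparison. In edgeR without that pig the smallest adjusted p was 0.057, and 1017 of the 1021 genes had an unadjusted p under 0.05. These genes were selected by the same contrast and the other pigs were used again. Their direction and unadjusted p are therefore no independent support. The count was 459 without fibre1 pig 1, 316 without pig 2, 454 without pig 5, 478 without pig 6, 1548 without pig 12, 325 without fibre2B pig 10 and 300 without pig 16, and 28 without fibre1 pigs 5 and 6 together, an alternative chosen after seeing the data. Of 33 called genes named here, the splicing genes below not among them, FAM53B, EHBP1L1, RAPGEF1, TMEM100 and HBB remained called without those 2 pigs. With the share of the 10 most abundant genes as a covariate 15 remained, namely MYH6, FAM53B, PROB1, EHBP1L1, KIF1C, RAPGEF1, ESRRA, GYS1, BTNL9, SLC19A2, BTAF1, TMEM100, HBB, DCN and DNAJB4.

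**Figure D2:**
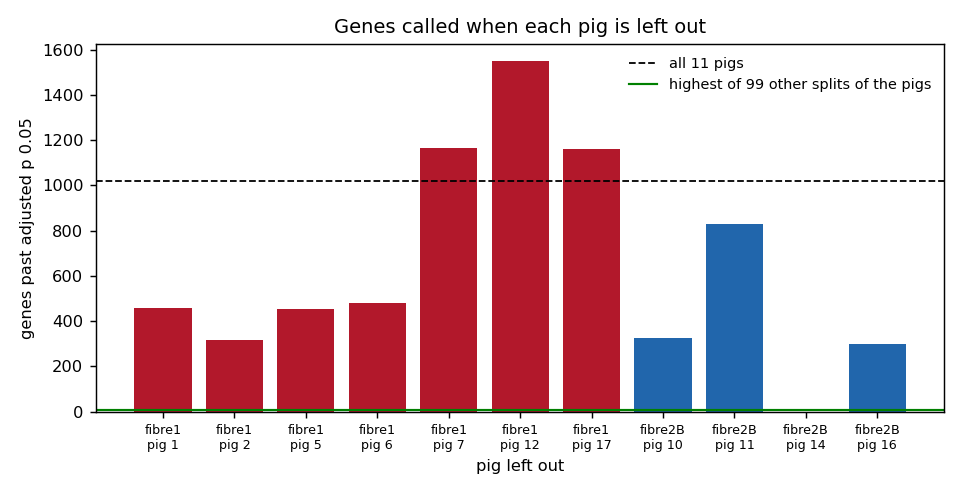
Genes past an adjusted p of 0.05 when the pig named on the x axis was left out, red for fibre1 and blue for fibre2B pigs, with a dashed line at the count with all 11 pigs (1021) and a green line at the highest count of 99 other splits of the pigs into 7 and 4 (5). The count ran from 0 without fibre2B pig 14 to 1548 without fibre1 pig 12.

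The count on the MYH6 ID was also tested by itself, in the place of the share of MYH7 among adult myosin heavy chains. No ID was listed as MYH7, MYH2, MYH1 or MYH4, and this stand-in was chosen after the values were seen. The ID listed as MYH6 ran from 2129 to 16410 CPM in fibre1 and from 370 to 1606 CPM in fibre2B, so it was higher in each of the 7 fibre1 pigs than in any fibre2B pig. The difference of means was 4428 CPM, with a two-sided exact permutation p of 0.0606 over 330 splits (0.121 adjusted over 2 tests), and on log2 of CPM plus 1 the difference was 2.17 with an exact p of 0.0030, the smallest the design allows. Without fibre1 pig 1, the highest pig, the difference was 2621 CPM (exact p = 0.014). The exact p was 0.043 without fibre1 pig 7 and 0.029 without pig 12. It was 0.15 without fibre2B pig 10 or pig 16, 0.175 without pig 11 and 0.183 without pig 14. It is not settled whether this ID holds reads of MYH6, MYH7 or both. Mitochondrially encoded genes took 8.72 ± 3.06% of counts in fibre1 (SD, n = 7) and 10.8 ± 3.45% in fibre2B (n = 4), a difference of -2.08 percentage points with an exact permutation p of 0.321, which is within the spread between pigs.

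The gene lists of contractile proteins were compared next. All 8 tested slow-fibre contractile and calcium genes had positive log2 fold changes, with a median of 0.89, but 0 of them passed over all genes tested and 0 passed adjusted over the list alone. The slow troponin genes TNNT1 and TNNI1 had log2 fold changes of 1.06 ± 0.41 (3669 ± 2224 against 1757 ± 865 CPM, adjusted p = 0.107) and 1.15 ± 0.45 (2373 ± 1604 against 1070 ± 593 CPM, adjusted p = 0.112), and ANKRD2 had 0.95 ± 0.39 (adjusted p = 0.126). Without fibre1 pig 1 TNNT1 had 0.69 (adjusted p = 0.149) and TNNI1 0.72 (0.165). With 1 surrogate variable TNNT1 (0.038) and TNNI1 (0.045) passed, as did TNNT1 with DESeq2 (0.032) and ANKRD2 without fibre1 pig 6 (0.035). Of the 9 fast-fibre genes tested, from 16 listed, 8 also had positive values, with a median of 0.39. Of these 9 genes 0 passed over all genes tested or adjusted over the list alone. MYH1, MYH2 and MYH4 had no ID and are missing from that list. Examples are MYBPC2 (0.82 ± 0.33), ATP2A1, the fast calcium pump (0.75 ± 0.34), and PVALB, the calcium buffer parvalbumin (0.36 ± 0.38, adjusted p = 0.564). MYH8, with 36301 ± 26592 against 13003 ± 3824 CPM (log2 fold change 1.48 ± 0.52, adjusted p = 0.085), and MYL11, a fast light chain (0.10 ± 0.24, adjusted p = 0.810), were named after their values were seen. MYL11 was not among the tested list members, though it is one of the 10 most abundant nuclear genes (46162 ± 12575 against 43052 ± 5865 CPM). Without fibre1 pigs 5 and 6, which had the highest share of counts on the 10 most abundant genes, MYBPC2 had 0.39, ATP2A1 0.33, MYH8 0.71 and MYL11 -0.0675 (adjusted p from 0.244 to 0.875). MYBPC2 (0.049) and MYH8 (0.032) passed without fibre1 pig 12, and MYH8 with quality weights (0.039). PVALB had 0.10 without fibre2B pig 11, 0.14 without pig 14 and 1.12 without pig 16, where it passed (0.048). By camera with a preset correlation of 0.01 the slow-fibre list was higher in fibre1 (adjusted p = 0.0092) and the fast-fibre list did not pass (adjusted p = 0.060). The call of the slow-fibre list was lost with an estimated correlation (adjusted p = 0.90 with an estimated correlation) and without fibre2B pig 14 (adjusted p = 0.114). The fast-fibre list was higher in fibre1 without fibre1 pig 1 (adjusted p = 0.027), pig 2 (0.0498) or pig 12 (0.042) and without fibre2B pig 10 (0.049) or pig 16 (0.015). The difference between the 2 lists was not tested.

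**Figure D3:**
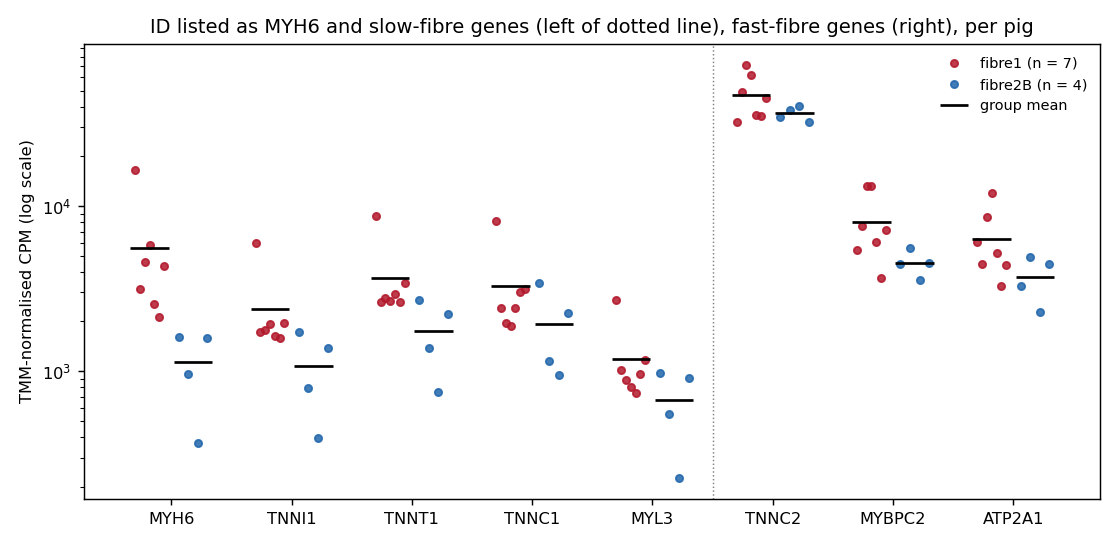
TMM-normalised CPM per pig on a log axis, for the ID listed as MYH6 and for slow-fibre genes on the left of the dotted line and fast-fibre genes on the right. Each point is a pig, red for fibre1 (n = 7) and blue for fibre2B (n = 4), black bars are group means, and fibre1 pig 1 was the highest pig for the MYH6 ID (16410 CPM) and for TNNT1 (8674 CPM).

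Genes of energy metabolism were listed as well. Of 16 citrate cycle and pyruvate dehydrogenase genes 15 had positive values (median 0.30) and 2 were higher in fibre1 over all genes tested, the same number as adjusted over the list alone. Of these OGDH, a subunit of the oxoglutarate dehydrogenase complex, had 246 ± 85.3 against 122 ± 23.9 CPM (log2 fold change 1.02 ± 0.26, adjusted p = 0.033), while PDHA1 had 0.67 ± 0.27 (adjusted p = 0.115). The list passed by camera (adjusted p = 0.0092) and lost its call with an estimated correlation (adjusted p = 0.90 with an estimated correlation) and without fibre2B pig 14 (adjusted p = 0.114). Of 42 nuclear-encoded oxidative phosphorylation genes NDUFA10 was higher in fibre1 (0.77 ± 0.22) and COX7A2 higher in fibre2B (-0.48 ± 0.13), 40 did not pass, and 0 passed adjusted over the list alone. The list did not pass by camera (adjusted p = 0.288), but was higher in fibre1 without fibre2B pig 10 (adjusted p = 0.014). Of 13 mitochondrially encoded protein genes 0 passed over all genes tested or adjusted over the list alone (camera adjusted p = 0.352), with ND2 at -0.54 ± 0.37 (-0.0529 without fibre2B pig 16 and -0.33 without fibre1 pigs 5 and 6). Of 21 fatty acid uptake and oxidation genes ECI2 was higher in fibre1 (0.69 ± 0.20), with 0 adjusted over the list alone. In that list PDK4, a kinase that inhibits pyruvate dehydrogenase, had -2.56 ± 0.77 (adjusted p = 0.054), and camera gave an adjusted p of 0.304. PDK4 had -1.23 without fibre2B pig 14 (adjusted p = 0.335), and it passed with DESeq2 (0.039) and without fibre1 pig 12 (0.026). Of 26 glycolysis and glycogen genes GYS1, muscle glycogen synthase, was higher in fibre1 (397 ± 79.7 against 218 ± 22.9 CPM, 0.86 ± 0.18, adjusted p = 0.019), again 1 adjusted over the list alone, and camera gave 0.304. GYS1 lost its call without fibre2B pig 14 (adjusted p = 0.070). OGDH lost its call without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 10, 14 or 16 (0.055 to 0.112). COX7A2 lost it without fibre1 pig 1, 2, 5, 6 or 7 or fibre2B pig 10, 14 or 16 (0.053 to 0.141). NDUFA10 (0.052 to 0.146) and ECI2 (0.058 to 0.152) lost theirs without fibre1 pig 1, 2, 5, 6 or 17 or any fibre2B pig. With no filter ECI2 (0.060), NDUFA10 (0.053) and COX7A2 (0.064) did not pass, nor did ECI2 with limma-voom (0.055).

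Regulators and growth genes went both ways. Of 25 tested fibre-type and mitochondrial regulators 3 were higher in fibre1 and 1 higher in fibre2B over all genes tested, and 3 and 3 adjusted over the list alone. MEF2C (0.88 ± 0.22), ESRRA (0.65 ± 0.16), a nuclear receptor that acts on mitochondrial genes, and VGLL2 (0.96 ± 0.27), named after its value was seen, were higher in fibre1, and FNIP1 was higher in fibre2B (-0.49 ± 0.14). PPARGC1A, a coactivator of mitochondrial genes, had 0.331 ± 0.166 against 0.518 ± 0.331 CPM (-0.57 ± 0.47, adjusted p = 0.446). Its log2 fold change was -0.87 without fibre2B pig 11 and -0.0941 without pig 14. Of 15 muscle growth and proteolysis genes CAPN1, the calpain 1 gene, was higher in fibre1 (0.76 ± 0.20) and MSTN and FST, the gene of the myostatin antagonist follistatin (-1.18 ± 0.30), were higher in fibre2B, with 2 and 3 adjusted over the list alone. Camera adjusted p were 0.342 and 0.861 for these lists. FNIP1 lost its call without any pig but fibre1 pig 12 (adjusted p from 0.052 to 0.122), and with upper-quartile factors (0.0501) and no filter (0.065). VGLL2 lost it without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 10, 14 or 16 (0.064 to 0.141), with no filter (0.053) and with limma-voom (0.062). MEF2C lost it without fibre1 pig 2, 5 or 6 or fibre2B pig 10, 14 or 16 (0.053 to 0.089). ESRRA lost it without fibre1 pig 1, 2 or 5 or fibre2B pig 11, 14 or 16 (0.051 to 0.107), and CAPN1 without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 10, 14 or 16 (0.051 to 0.118). Without fibre2B pig 14 FST had -0.61 (0.127), and it also lost its call without fibre1 pig 1, 2 or 5 or fibre2B pig 16 (0.051 to 0.062).

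Markers of other cell types were measured beside the muscle genes. Of 18 fibroblast and extracellular matrix markers, the proteoglycan genes DCN (135 ± 35.0 against 297 ± 98.6 CPM, -1.13 ± 0.23, adjusted p = 0.019) and LUM (-1.05 ± 0.25, adjusted p = 0.026) were higher in fibre2B, with 2 adjusted over the list alone (camera adjusted p = 0.288). Of 7 satellite cell markers VCAM1 was higher in fibre2B (10.1 ± 3.27 against 20.3 ± 9.66 CPM), as it was adjusted over the list alone, where the count is 1. Camera gave the list an adjusted p of 0.169, and 0.049 without fibre2B pig 16, lower in fibre1. Of 10 smooth muscle and pericyte markers KCNJ8 was higher in fibre2B (-0.78 ± 0.21), and adjusted over the list alone the count was also 1 (camera adjusted p = 0.579). Of 11 adipocyte markers RBP4 was higher in fibre2B (0.428 ± 0.415 against 2.78 ± 2.66 CPM, -2.67 ± 0.71), again with 1 adjusted over the list alone (camera adjusted p = 0.794). Of 10 endothelial markers 0 passed over all genes tested, and adjusted over the list alone 3 were higher in fibre1 and 1 in fibre2B, with TIE1 at 0.78 ± 0.24 (camera adjusted p = 0.342). TIE1 passed with DESeq2 (0.017), 1 surrogate variable (0.016) and the covariate (0.034) and without fibre1 pig 12 (0.048). Of 12 immune cell markers 0 passed over all genes tested or adjusted over the list alone, with CD68 at -0.99 ± 0.44 and C1QA at -0.70 ± 0.33 (camera adjusted p = 0.304). Without fibre2B pig 14 CD68 had -0.36 (adjusted p = 0.647) and C1QA -0.24 (0.678). Of 3 tested blood markers HBB was higher in fibre2B, and 2 passed adjusted over the list alone, with ALAS2, a gene of heme synthesis in red cells, at -1.14 ± 0.42, which passed with quality weights (0.024) and the covariate (0.045). Of 2 tested nerve markers 0 passed over all genes tested, with EGR2 at -0.60 ± 0.58 (0.16 without fibre2B pig 11 and -0.93 without pig 16), and 0 passed adjusted over the list alone. These last 2 lists had fewer than 5 tested members and were not tested as lists. The VCAM1 call (adjusted p = 0.049) was lost with upper-quartile factors, no filter, limma-voom with or without quality weights and the covariate, and without any pig but fibre1 pig 12 or fibre2B pig 11 (adjusted p from 0.053 to 0.198 over these settings). KCNJ8 lost its call without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 10, 11 or 14 (0.053 to 0.148). RBP4 lost it without fibre1 pig 1, 2, 5 or 6 or fibre2B pig 11 or 14 (0.061 to 0.152). LUM lost it without fibre1 pig 2 or fibre2B pig 11 or 14 (0.051 to 0.085), and DCN without fibre2B pig 14 (0.070). Without that pig KCNJ8 had -0.51. With all pigs RBP4 did not pass with limma-voom (0.086) or with quality weights (0.116), nor KCNJ8 with limma-voom (0.051).

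Stress and translation genes closed the lists. Of 14 interferon-stimulated genes 13 had negative values (median -1.09), IFIT2 was higher in fibre2B over all genes tested, and 6 passed adjusted over the list alone. IFIT1 had 2.23 ± 1.15 against 6.86 ± 6.82 CPM (-1.59 ± 0.49, adjusted p = 0.058), with fibre2B pig 14 at 17.1 CPM. Without that pig IFIT1 had -0.60 (adjusted p = 0.392), and it passed with DESeq2 (0.014) and 1 surrogate variable (0.040) and without fibre1 pig 7 (0.048) or pig 12 (0.043). The list passed by camera (adjusted p = 0.013), but not with an estimated correlation (adjusted p = 0.90 with an estimated correlation) nor without fibre2B pig 14 (adjusted p = 0.266) or without fibre1 pigs 5 and 6 (adjusted p = 0.094). Of 24 cytosolic ribosomal protein genes 19 had negative values (median -0.20) and 0 passed over all genes tested or adjusted over the list alone, with RPL11 at -0.49 ± 0.15. RPL11 passed with DESeq2 (0.013), quality weights (0.046) and 1 surrogate variable (0.042) and without fibre1 pig 12 (0.042). That list passed by camera (adjusted p = 0.020), not with an estimated correlation (adjusted p = 0.90 with an estimated correlation), nor without fibre1 pig 1 (0.081) or pig 7 (0.058) or without fibre2B pig 10 (0.155) or pig 14 (0.114). Of 15 heat shock genes HSPA1L was higher in fibre1 and DNAJB4 (-1.26 ± 0.23) higher in fibre2B, as they were adjusted over the list alone, with a camera adjusted p of 0.886. DNAJB4 lost its call without fibre2B pig 14 (adjusted p = 0.057). Of 12 immediate early genes 0 passed over all genes tested or adjusted over the list alone, with KLF4 at -1.14 ± 0.34 (adjusted p = 0.051) and a camera adjusted p of 0.973. KLF4 passed with the CPM filter (0.047), DESeq2 (0.017), quality weights (0.034) and 1 surrogate variable (0.048), and without fibre1 pig 12 (0.022) or pig 17 (0.034). In the adipocyte list the median was 0.14 and the mean -0.07, and in the immediate early list 0.04 and -0.10. Camera's direction was up in both.

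**Figure D4:**
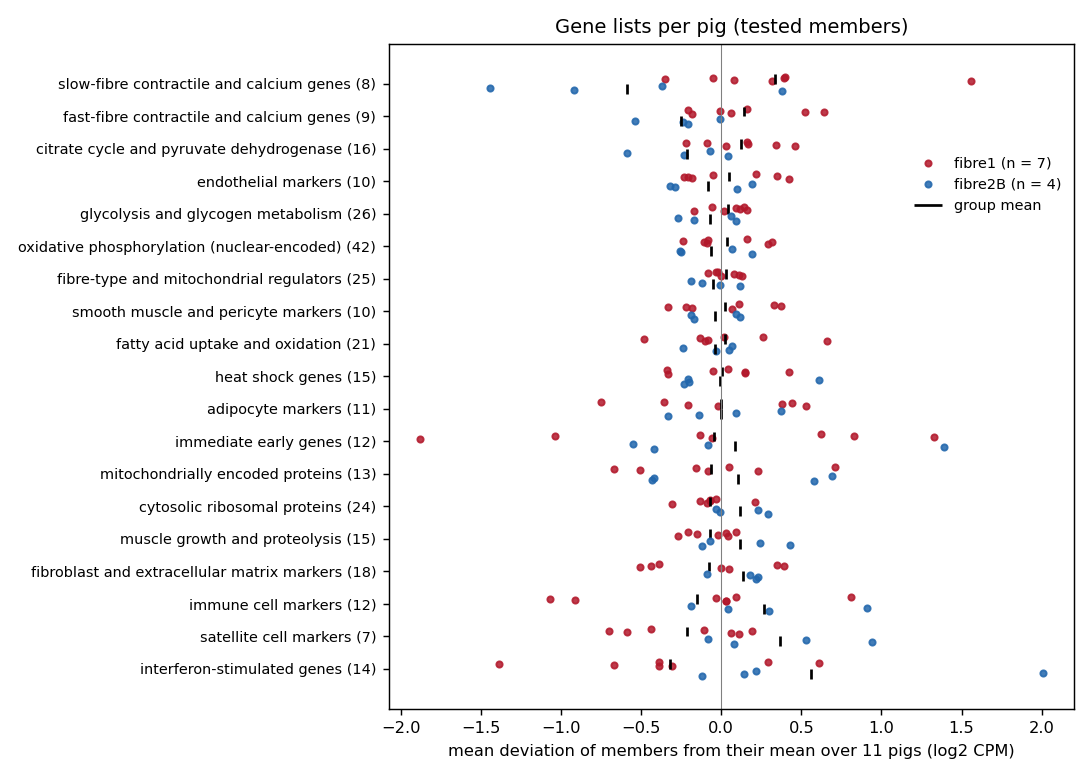
Mean deviation of the tested members of each list from their mean over the 11 pigs, in log2 CPM, for each of the 19 lists with at least 5 tested members. Each point is a pig, red for fibre1 (n = 7) and blue for fibre2B (n = 4), black bars are group means, and the right-most point of the interferon-stimulated list is fibre2B pig 14 at 2.01.

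None of the 19 lists passed an exact permutation test of its mean log2 CPM, chosen after seeing the data, where the smallest adjusted p was 0.278. The blood markers, outside that family, had a list mean lower in fibre1 by exact permutation (p = 0.039, unadjusted, 3 members). Without fibre2B pig 14 camera called 0 lists, and its smallest adjusted p was 0.114, shared by the slow-fibre, citrate cycle, ribosomal and mitochondrially encoded lists.

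The second comparison asked whether isoforms differ. SRF, the serum response factor gene, had an isoform at 80.4 ± 17.2 CPM in fibre1 (SD, n = 7) and 34.3 ± 3.47 CPM in fibre2B (n = 4), a log2 fold change of 1.23 ± 0.18 (SE; edgeR adjusted p = 0.023). Isoforms of BRPF1 (1.05 ± 0.16), RAPGEF1 (1.54 ± 0.24), NACC1 (1.45 ± 0.22) and STX16 (1.95 ± 0.30) were higher in fibre1. Isoforms of FGFR1OP2 (-1.10 ± 0.15), TMEM100 (-1.45 ± 0.21), MTR, the methionine synthase gene (-0.97 ± 0.15), ODR4 (-0.99 ± 0.15) and RNF128 (-0.78 ± 0.13) were higher in fibre2B. In all, 658 of 12212 isoforms passed, 340 higher in fibre1 and 318 higher in fibre2B. Only 665 genes had at least 2 tested isoforms, with a median of 2. Most tested isoforms were therefore the only tested one of their gene, and their test largely repeats that of the gene. The RAPGEF1 isoform had 69.1 against 23.7 CPM and its gene 68.9 against 23.7 CPM. They came from 654 genes, of which 642 were also called by gene. EdgeR called 0 isoforms without fibre2B pig 14 (2386 at an unadjusted p under 0.05), without fibre1 pig 2 (2830) or without fibre2B pig 16 (2814), 1 without fibre2B pig 10, 83 without fibre1 pig 1, 105 without pig 5, 238 without pig 6, 368 without fibre2B pig 11 and 1063 without fibre1 pig 12. The isoforms named here lost their calls without fibre1 pig 2 or fibre2B pig 10, 14 or 16 (adjusted p from 0.053 to 0.086), and without fibre1 pigs 5 and 6 together (0.056 to 0.069).

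The third comparison asked whether the shares of isoforms within a gene differ. In SUPT5H, which encodes a transcription elongation factor, the isoform ENSSSCT00000030229 held 49.2 ± 30.3% of the counts in fibre1 (SD, n = 7) and was at 0 in the 4 fibre2B pigs and in fibre1 pig 6. The counts of 322 to 507 on the tested isoforms in the fibre2B pigs allow shares of up to 0.592% to 0.932%, for counting error only. In RENBP the isoform ENSSSCT00000033543 held 15.5 ± 8.69% against 0.725 ± 1.45%, and in TRAPPC9 the isoform ENSSSCT00000006515 held 9.49 ± 7.15% in fibre1 and was at 0 in the 4 fibre2B pigs, on 83 to 119 counts, and in fibre1 pigs 5 and 6, on 147 and 234 counts. By edgeR's gene-level test 5 of 665 genes passed, among them SUPT5H and RENBP (adjusted p = 0.0098), ENSSSCG00000010712 (adjusted p = 0.018), named after its value was seen, and TRAPPC9 (adjusted p = 0.030). MIB2 did not (adjusted p = 0.069), except without fibre1 pig 6 (0.040) or pig 12 (0.037). SUPT5H lost its call without fibre1 pig 2 or 17 or fibre2B pig 10 or 11 (0.053 to 0.109). RENBP lost it by the Simes-adjusted test (0.572), without fibre1 pigs 5 and 6, and without fibre1 pig 2, 6 or 17 or fibre2B pig 10, 11 or 14 (0.081 or more). TRAPPC9 lost it by the Simes-adjusted test (0.224), with the CPM filter (0.999), and without fibre1 pig 1, 2, 7, 12 or 17 or any fibre2B pig (0.054 to 0.255). The edgeR count was 0 without fibre1 pig 2 (37 at an unadjusted p under 0.05), fibre1 pig 17 (44), fibre2B pig 10 (60) or fibre2B pig 11 (68), 2 without fibre1 pig 1, fibre2B pig 14 or fibre2B pig 16, and 8 without fibre1 pig 12, and the Simes-adjusted test called 2. The assignment of 50-cycle single-end reads to isoforms of 1 gene is uncertain, and its error is not in these counts.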

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

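The tests of other splits of the pigs, of the covariate, of the cell-type markers and of immune cells were chosen after the results were seen, and the test of depth was set before its result.

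The highest or lowest pig was compared with the rest of its group in 164 cases. For normally spread values chance would set about 1 in 20 far apart, or 8.2. Here 20 values stood far apart. Fibre2B pig 14 held 8 of them: IFIT1 at 17.1 CPM, IFIT2 at 12.6, SAMD9 at 24.2, PDK4 at 707, FST at 41.0 and CD68 at 6.30 CPM, and mean deviations of 2.01 log2 units for interferon-stimulated and 0.61 for heat shock genes. Fibre1 pig 1 held 5: the MYH6 ID at 16410 CPM, TNNT1 at 8674, TNNI1 at 5998 and ESRRA at 122 CPM, and a slow-fibre mean deviation of 1.56. Fibre1 pig 7 stood apart in LUM at 60.9, RBP4 at 1.29 and MSTN at 4.59 CPM. Fibre1 pig 12 stood apart in MEF2C at 47.9 and FNIP1 at 33.5 CPM and fibre2B pig 10 in ANKRD2 at 50.9 CPM, and fibre2B pig 16 had the lowest fibroblast mean deviation of its group, -0.0902. Single genes were compared as CPM without logarithms, and each that stood apart did so as the highest of its group. Several lists also hold genes compared singly. The count of 20 against 8.2 therefore does not show an excess over chance.

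The 1021 genes and 658 isoforms called were set against 100 of the 330 splits of the pigs into 7 and 4. Only the real split (1 of 100) gave as many, and the highest other split gave 5 genes and 3 isoforms. Chance is thus unlikely for both counts, but not excluded, since the remaining splits were not run. These counts are not independent, as 642 of the 654 genes with a called isoform were also called by gene. A few abundant genes taking most of the counts were tested with their share as a covariate. The median change of the called genes kept 0.893 of its size (0.73 against 0.82 log2 units), while the count fell to 460. Over these genes, which were chosen by the same contrast, this argues against that share as the whole source. As a part of the source it stays open. Fibre histology, the design's own difference, was not tested apart from the groups and stays open, as do GC content and RNA quality, not analysed here. For usage, 11 of the 100 splits gave at least 5 genes, with 9 as the highest other, so chance cannot be excluded. For lists, 83 gave at least 4, with 12 as the highest other and 6 as the median of the others. The real split thus called fewer lists than other splits commonly do, so chance cannot be excluded there either.

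Contractile genes had mostly positive log2 changes, while several markers of other cell types were higher in fibre2B. A larger share of muscle fibres in the fibre1 samples would lower the markers of all other cell types alike. Of 8 lists of such markers 5 had a lower mean in fibre1, with differences from -1.23 for blood to 0.13 for endothelium. The spread of these differences was not larger than other splits of the pigs give (exact permutation p = 0.161). In that test the blood and nerve lists, with 3 and 2 tested genes, counted as much as the larger lists. Their noise can hide a spread among the others. A difference in the share of muscle fibres therefore stays open. A change in single cell types and fibre type itself, which was not tested apart from the groups, stay open too.

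Interferon-stimulated genes were highest in fibre2B pig 14. Thinning every library to the lowest total left its excess over the next pig at 1.04 times its size (1.40 against 1.35 log2 units), which argues against its lower depth. Fibre1 pig 12, picked as the pig with the next highest immune markers, lay 0.10 log2 units below pig 14 in these. It lay 1.72 below in interferon-stimulated genes. The gaps differ by 1.62 ± 0.31 (SE over 14 and 12 genes, which are not independent). In pig 12 a similar immune mean (0.81 against 0.91 in pig 14) thus went without such interferon-stimulated genes. That rests on 1 pig picked for its immune mean, and every other pig had an immune mean of 0.30 or less. More immune cells of every kind are therefore not excluded. CD68 (6.30 against 2.27 CPM) was the 1 immune marker of 12 with a gap over 1.25 log2 units, the interferon gap less 2 times its SE, and of the rest some were higher in pig 14, as C1QA (53.1 against 30.4 CPM) and PTPRC (8.29 against 5.38 CPM), and 6 were lower, among them CSF1R (-0.32), LYZ (-0.50), LAPTM5 (-0.59) and CD3D (-0.86 log2 units), so more immune cells of one kind are neither shown nor excluded. An interferon response of that animal may be an explanation too, and it was not tested.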

How the results depend on the processing

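The settings without fibre1 pigs 5 and 6, with the covariate, with another tool and no fibre2B pig 14, for the MYH6 ID and with permuted list means were chosen after the results were seen. No paired analysis was possible because the groups share no replicate number. The planned share of MYH7, with its alternatives, was not run, since 0 IDs were listed under that name. Genes called were 1021, against 1759 with DESeq2, 1748 with limma-voom and quality weights, 1628 with 1 surrogate variable, 460 with the covariate, 28 without fibre1 pigs 5 and 6, 129 with 1 surrogate variable and no fibre2B pig 14, and 0 (2436 at an unadjusted p under 0.05) to 1548 leaving out each pig. The other 9 settings stayed within 1.5 times. Isoforms called were 658, against 326 with no filter, 1723 with DESeq2, 1400 with quality weights, 1 without fibre1 pigs 5 and 6, and 0 to 1063 leaving out each pig. Usage calls were 5, against 3 with the CPM filter, 2 by the Simes-adjusted test, 3 without fibre1 pigs 5 and 6, and 0 to 8 leaving out each pig. Lists called were 4, against 0 with an estimated correlation (smallest adjusted p 0.899), 0 with fry (0.319), 0 with permuted list means (0.278), and 0 to 6 leaving out each pig. The MYH6 difference was 2.17 on log2 of CPM plus 1 and 2621 to 5001 CPM leaving out each pig, and that of the mitochondrial share -3.17 to -0.774 percentage points, never past the threshold. Of 64 named genes, the splicing genes below not among them, 61 kept their direction in every setting run. The exceptions were MYL11 (-0.0675 without fibre1 pigs 5 and 6, -0.11 with the covariate, -0.00399 with 1 surrogate variable and no fibre2B pig 14, and -0.0210 to 0.19 leaving out each pig), EGR2 (0.20 with quality weights and no fibre2B pig 14, and -0.93 to 0.16 leaving out each pig) and PPARGC1A (0.10 with 1 surrogate variable and no fibre2B pig 14), none past the threshold there. EHBP1L1, FAM53B, RAPGEF1 and TMEM100 lost their call only in edgeR without fibre2B pig 14. Fewer pigs leave fewer degrees of freedom, and otherwise the cause was not tested.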

Other observations

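The list of splicing genes was chosen after called genes had been seen, and its test was set before its own values were computed. The tests without single pigs and without fibre1 pigs 5 and 6 were chosen after its result.

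Genes of pre-mRNA splicing were among the called genes. CLK4, PRPF39 and RSRC2 drew attention to them and were left out of the list. Of 36 tested genes of a list of 50, 9 were higher in fibre2B and 0 in fibre1. Among them CLK1, a kinase of splicing factors, had a log2 fold change of -1.22 ± 0.28 (SE; edgeR adjusted p = 0.024), SRSF11 -0.84 ± 0.21, SRSF1 -0.78 ± 0.19, LUC7L3 -0.75 ± 0.18, TRA2B -0.74 ± 0.16, SRSF3 -0.63 ± 0.17, RBM39 -0.60 ± 0.14 and DDX46 -0.53 ± 0.15. SNRNP200 (0.79 ± 0.28, adjusted p = 0.086) and PRPF6 (0.64 ± 0.22, adjusted p = 0.077) had positive values and did not pass. Without fibre2B pig 14 edgeR called 0 genes, these included.

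A hypothesis is that splicing factor genes may be higher in fibre2B as a class. The mean deviation of the list was -0.08 ± 0.13 log2 units in fibre1 (SD, n = 7) and 0.15 ± 0.08 in fibre2B (n = 4). The difference was -0.23, with a two-sided exact permutation p of 0.0152, unadjusted. The list was prompted by splicing genes called in this same contrast, and dropping the prompting genes does not undo that choice. The p values of this list, with or without pigs left out, therefore cannot decide whether the class differs. Leaving out each pig gave exact permutation p from 0.0048 to 0.058, the highest and the only one over 0.05 without fibre2B pig 14, and without fibre1 pigs 5 and 6 it was 0.056. RNA quality and GC content were not analysed here and stay open.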
